A study of Drosophila melanogaster with 19 samples.

How the data were processed

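RNA was sequenced from neurons of the optic lobe, the visual part of the brain, of adult Drosophila melanogaster aged 3 to 6 days. Per the labels' protocols, a Gal4 driver line for each cell type expressed a red fluorescent protein in the nuclei of that type, and labelled cells were sorted by fluorescence. cDNA was made with SMART-Seq v4 and libraries with Nextera XT, per the same protocols. Per the submitters' processing notes, the tools were Trimmomatic 0.32, STAR 2.5.2 and HTSeq 0.6.1, with genome build BDGP6. The strand setting of the counting is not stated. These library kits do not mark strand, so reads over bases that a gene shares with a gene on the other strand cannot be told apart. Over 10 percent of exon bases lie in exons of a gene on the other strand for 2040 genes.

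The deposited values are raw read counts per gene, without normalization, for 17558 FlyBase gene identifiers, with 5 summary lines of the counting that are not genes. The table has 3 numbered libraries for each of 19 GEO samples, 57 in all, which are 17 single types, sorted neurons and the T1 and Tm1 mixture. GEO lists 1 sample per cell type, so the p-values measure the spread between the libraries of a sample, which may be technical. In the 57 pairs of libraries of a sample, counts differed by more than sampling noise (chi-square per degree of freedom from 11.61 to 270.1), and each library was used as a unit. That check covers counting error only, and separately amplified libraries of 1 sample would also exceed it, so it does not show that the libraries are biological replicates. Symbols came from a gene name table for 17252 identifiers and from synonyms in another table for 1, and 305 identifiers had no symbol. Coordinates, exon lengths and overlaps came from Ensembl annotation release 115, whose gene models can differ from those used for the counts, so overlaps describe the models of that release. Genes whose symbols were not matched, VAChT, ap, scro and para among them, were not analysed here.

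Reads in genes ranged from 0.602 M (mega) reads in T2 library 3 to 72.677 M in mixture library 1, with a median of 21.76 M, and genes with a read from 6252 to 12937 per library. A level of 0 in all libraries of a group allows 3 counts over the group, which is 0.47 CPM in T2 and at most 0.068 CPM, the value of Lawf1, in the other groups. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

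Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 12569, scaled with TMM and fitted with a robust quasi-likelihood model with 1 coefficient per group over the 57 libraries. The Benjamini-Hochberg threshold was 0.05, with an absolute log2 fold change of 1 or more in addition for single types and for pairs of types that share a name stem. The comparisons were an F test over the 17 types, each type against the mean of the other 16, the mean of the 17 types against sorted neurons, the mixture against T1, and 4 pairs that share a name stem. Tm types were compared with T types and with Dm types with the type as the unit, libraries summed. Sums, correlations and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Profiles were compared as log2(CPM + 1), and correlations between genes used 100000 permutations. The planned correlation of ChAT with VAChT was replaced by one of ChAT with ChT.

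The gene lists held synthesis, release or transport genes of acetylcholine, glutamate, GABA, histamine and monoamines, and receptors for acetylcholine (nicotinic and muscarinic), GABA, glutamate, histamine and monoamines. Others held homeodomain and other transcription factors, Dpr and DIP, Beat and Side and other adhesion proteins, neuropeptides, ion channels, innexins, pan-neuronal, clock and activity-regulated genes, and ribosomal, mitochondrially encoded and mitochondrial ribosomal genes. Marker lists covered glia, photoreceptors, hemocytes, fat body and yolk, muscle, trachea, stress, sex-biased transcripts and immune peptides. The spread of a list was its median between-type SD, placed among 10000 random lists of its size matched on mean expression in 50 bins. Lists of at least 5 tested genes were compared by camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation.

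The lists, the comparisons, the first alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the transmitter genes and bsh and hth. For each type it names the 2 genes of largest fold change with at least 20 CPM and every library above every library of the other types, and the listed transcription factor of largest fold change. It also names the leading genes of each other comparison and up to 4 members of each list with the largest spread, with genes left out in the order of rank. Outside the rule, the pan-neuronal and glia genes given for T1, acj6, CG14877, and Drgx and eys between name classes, were chosen after their values were seen. RluA-1 is among the leading genes of the mixture comparison, but was named out of the order of rank after its values were seen.

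The fits were tested on simulated counts with the depths of these libraries, with 50 genes changed per fold size. The changed genes were drawn from the more abundant genes, and levels before the change were the same in all groups. Recovery was counted by adjusted p and direction alone, without the minimum log2 fold change of 1 used for single types and name pairs. Genes raised 2-fold lay near that minimum, with a median fitted log2 value of 1 in C2 and 0.99 in T2. Part of the 2-fold genes would thus not be called under it. C2 against the other types recovered 92 percent of genes raised 2-fold, 100 percent raised 4-fold, 90 percent lowered to 0.5 and 100 percent lowered to 0.25, and called 0.113 percent of unchanged genes. T2 against the others recovered 100, 100, 86 and 100 percent and called 0.103 percent of unchanged genes. The types against sorted neurons gave 88, 100, 98 and 100 percent, with 0.103 percent of unchanged genes called. The mixture against T1 gave 80, 98, 84 and 100 percent (0.103 percent), and Tm5ab against Tm5c 80, 100, 80 and 100 percent (0.0656 percent). Tm against T types recovered 8 percent raised 4-fold, 94 percent raised 64-fold, 12 percent lowered to 0.25 and 98 percent lowered to 0.0156, with 0.0798 percent of unchanged genes called. Tm against Dm types recovered 6, 96, 18 and 100 percent, with 0.00959 percent called. So changes of 4-fold between name classes were mostly missed.

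Other settings tried were DESeq2 1.42.0 size factors, the DESeq2 test, no filter on low counts, limma-voom with sample weights, leaving out each library or type, 1 profile per type, the library number as a block, fits of 2 groups alone, limma on mean log levels for the name classes, pseudocounts of 0.1 and 5, the 500 most variable genes for similarity, and an estimated correlation. Fits without T2, libraries thinned to 602175 reads, and an arithmetic mean over the types were chosen after seeing the data.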

Results

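The series compares 17 single neuron types of the adult fly optic lobe with each other and with sorted neurons, which serve as the control, and adds a line that labels T1 and Tm1 cells together. The types are C2, C3, Dm2, Dm8, Dm12, Lawf1, Lawf2, Mi1, T1, T2, T3, T5, Tm2, Tm3, Tm5ab, Tm5c and Tm9, and each of the 19 groups has 3 libraries. Levels are TMM-scaled counts per M reads (CPM, M for mega), given as mean ± SD with n = 3 libraries. The T2 libraries held 9444398, 2531086 and 602175 reads in genes and the mixture libraries 72677109, 21784808 and 6147470, against a median of 21.76 M reads over the 57 libraries.

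**Figure D1:**
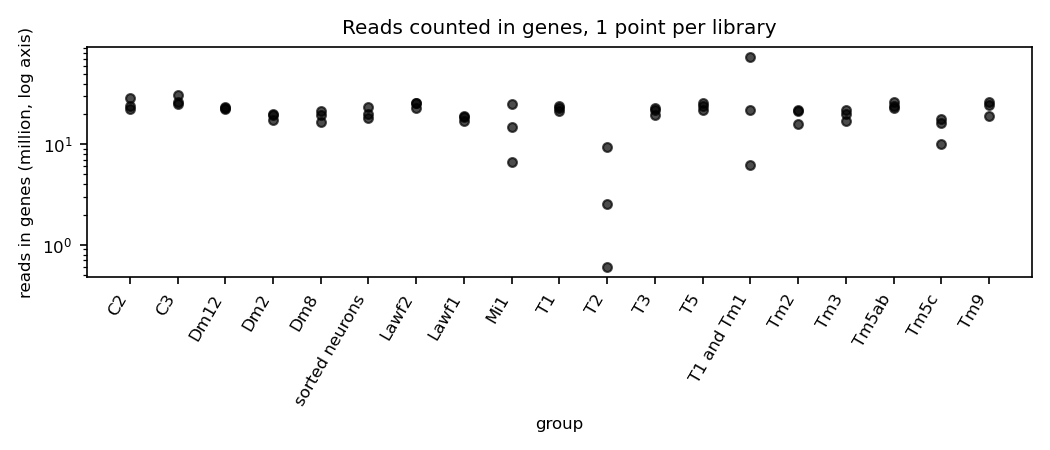
Reads counted in genes on a log axis for the 3 libraries of each of the 19 groups. T2 library 3 is the shallowest with 602175 reads and the first mixture library the deepest with 72677109.

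The Mi1 label was checked on bsh and hth, homeodomain genes known from Mi1 neurons, and the labels of the other types were not checked in this way. bsh stood at 649 ± 68.3 CPM in Mi1 and at no more than 3.13 in the other 16 types. hth stood at 1495 ± 145 in Mi1 and was higher in 1 type, Lawf1, at 5019 ± 452.

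Transmitter genes split the types into sets. ChAT (FBgn0000303, chromosome 3R, 18705501 to 18732344 in BDGP6), the enzyme that makes acetylcholine, lay between 332 ± 8.78 CPM in Lawf1 and 1716 ± 80.8 in Tm9 in 11 types, which are Dm2, Lawf1, Lawf2, Mi1, T2, T3, T5, Tm2, Tm3, Tm5ab and Tm9. In C2, C3, Dm8, Dm12, T1 and Tm5c it was at or below 7.44, beside 459 ± 45.2 in sorted neurons. VGlut (FBgn0031424, 2L, 2400295 to 2410662), the vesicular glutamate transporter, reached 3758 ± 299 in Dm8, 2746 ± 180 in Dm12 and 2292 ± 599 in Tm5c. The next highest VGlut level was 131 ± 73.7 in Tm3, and sorted neurons had 774 ± 169. Gad1 (FBgn0004516, 3L, 4074077 to 4088744), the enzyme that makes GABA, reached 13280 ± 2220 in C3 and 3915 ± 418 in C2, followed by 148 ± 68.9 in T2, with 1468 ± 123 in sorted neurons. T1 had none of the 3 genes at such levels, with ChAT at 7.44 ± 2.72, VGlut at 20.1 ± 13.3 and Gad1 at 25.1 ± 16.2. Of the exon bases of ChAT, 15.1 percent lie in exons of VAChT, and reads there cannot be assigned to 1 of the genes.

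The vesicular GABA transporter gene VGAT was measured from 50.9 CPM in Lawf1 to 244 ± 20.1 in C2 and 368 ± 33.6 in C3. Over the 15 types other than C2 and C3, Gad1 and VGAT were correlated (Pearson r = 0.62, 2-sided permutation p = 0.0123, adjusted p = 0.0246 over the 2 relations computed). Spearman's rho was 0.68 (permutation p = 0.00703, adjusted p = 0.0141), and r was 0.64 without T1 and T2, the types farthest from the median Gad1 level. These 15 types were taken for Gad1 under 1000 CPM, and the median Gad1 level over all single types was 5.68 CPM. The correlation is thus among mostly low Gad1 levels, whose source was not tested. It does not show that the types regulate the 2 genes together. The choline transporter gene ChT was highest in T2 at 2281 ± 738, then in Lawf2 at 858 ± 80.4, and 69.5 percent of its exon bases are shared with CG46318. Over the 11 types with high ChAT, ChAT and ChT gave r = -0.30 (permutation p = 0.373, adjusted p = 0.373) and rho = -0.51 (permutation p = 0.113, adjusted p = 0.113), and r was -0.39 without Tm9 and Lawf1. That relation did not pass the threshold.

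The vesicular monoamine transporter gene Vmat stood at 2184 ± 1480 CPM in Dm2 against at most 7.44 in the other types, though 26.2 percent of its exon bases lie in exons of CG13330 on the other strand. Dm2 was also highest for ple (tyrosine hydroxylase) at 328 ± 192 and for the dopamine transporter gene DAT at 136 ± 103. The serotonin transporter gene SerT was at 300.2 ± 11.3 in Lawf1 and at most 0.902 elsewhere, while Trhn, which acts in serotonin synthesis, peaked at 31.2 ± 6.62 in Tm5ab. Ddc, a decarboxylase of dopamine and serotonin synthesis, was above 100 CPM in 11 types and highest in T3 at 819.8 ± 57.1. Tbh, the enzyme that makes octopamine, was above 100 CPM in 5 types, T3 (425 ± 103), T2 (324 ± 160), Dm8 (246 ± 32.4), Tm5ab (227 ± 10.3) and Tm3 (194 ± 32.6). Tdc2, which makes tyramine, was at most 3.86 in a type, and Pu, which makes a hydroxylase cofactor, was highest in T2 at 74.3 ± 5.25.

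Histamine is the transmitter of photoreceptors, and its synthesis and transport genes were low in the types. Hdc, the synthesis enzyme, was at most 3.02 CPM, Balat at most 3.06, CG30345 at most 2.61, ebony (e) at most 3.91 and tan (t) at most 1.57, while the carcinine transporter gene CarT reached 45.9 ± 6.04 in C3. The histamine-gated chloride channel gene ort reached 1347 ± 399 in Tm5c, 711 ± 28 in Tm5ab, 686 ± 79.2 in Dm8 and 572 ± 69.1 in T1, followed by 161 ± 27.8 in Tm2. HisCl1, a second such channel gene, was highest in T2 at 50.5 ± 35.4. Of the exon bases of Balat, 98.5 percent lie in exons of asRNA:CR43469 on the other strand, and of those of CG30345 24.2 percent lie in a Burdock transposable element.

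**Figure D2:**
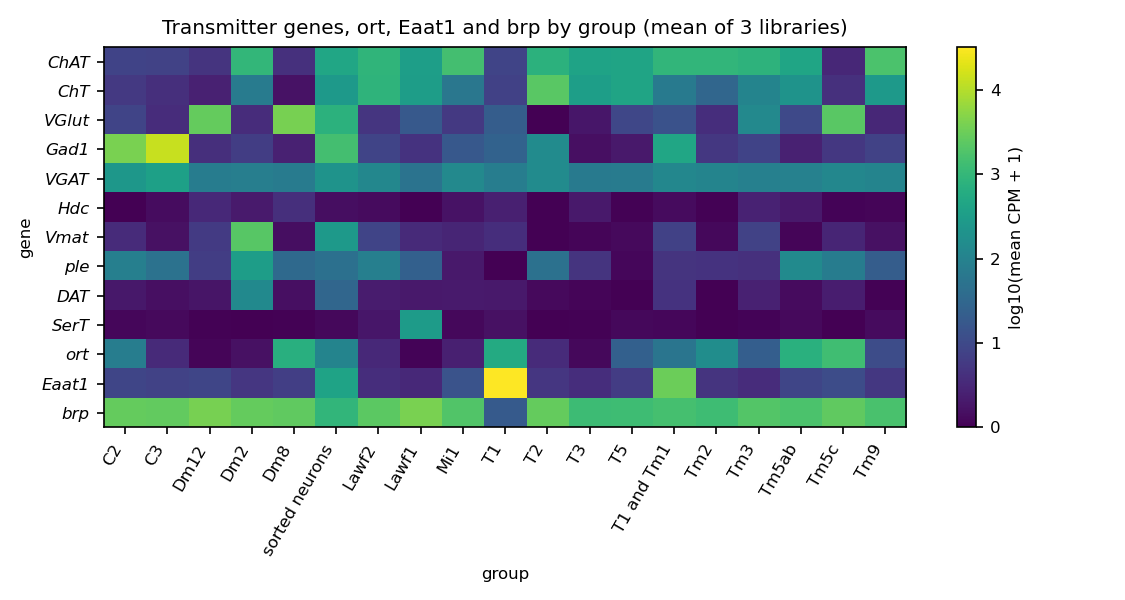
Mean level of 3 libraries as log10(CPM + 1), as colour, for 13 genes (vertical axis) in the 19 groups (horizontal axis). ChAT, VGlut and Gad1 are high in separate sets of types, and T1 has none of these at a high level.

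T1 stood apart in a transporter and in a synaptic protein. Eaat1 (FBgn0026439, 2L, 9333567 to 9341925), a glutamate transporter gene best known from glia, stood at 32110 ± 4550 CPM in T1 and at or below 13.3 in the other 16 types, a log2 fold change of 12.55 (SE 0.20, adjusted p = 1.93e-47) in edgeR. brp (FBgn0259246, 2R, 9503765 to 9541565), a scaffold protein of presynaptic active zones, stood at 18.04 ± 8.96 in T1 and at or above 1234 in the other types, a log2 fold change of -6.91 (SE 0.25, adjusted p = 8.48e-30). Rim, which acts at the same active zones, was at 267 ± 48 in T1 against a median of 2546 over the other types. Of the 15 pan-neuronal genes other than brp, 12 passed an edgeR adjusted p of 0.05 in T1, 8 lower and 4 higher. Lower, with log2 fold changes, were Rim (-3.45), Syx1A (-2.06), comt (-1.58), cpx (-1.58), fne (-0.96), Snap25 (-0.65), Syt1 (-0.57) and Rbp9 (-0.45). Higher were Appl (1.67), futsch (0.65), CadN (0.62) and unc-13 (0.29), while elav (-0.04), nSyb (-0.04) and Csp (-0.27) did not pass. Of 18 glia genes other than Eaat1, 6 were higher in T1 at that threshold, e (1.996), CG9686 (1.85), alrm (1.58), Gs2 (1.42), Gat (1.21) and Eaat2 (0.82), and 2 were lower, Tret1-1 (-0.80) and CG6126, with no read in T1 (up to 0.0454 CPM) against a median of 1.204 in the other types. T1 had alrm at 13.6 ± 2.31 CPM and Gs2 at 111 ± 37.1, above at most 9.06 and 71.2 in the other types, and repo, at 3.75 ± 1.67, did not pass.

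**Figure D3:**
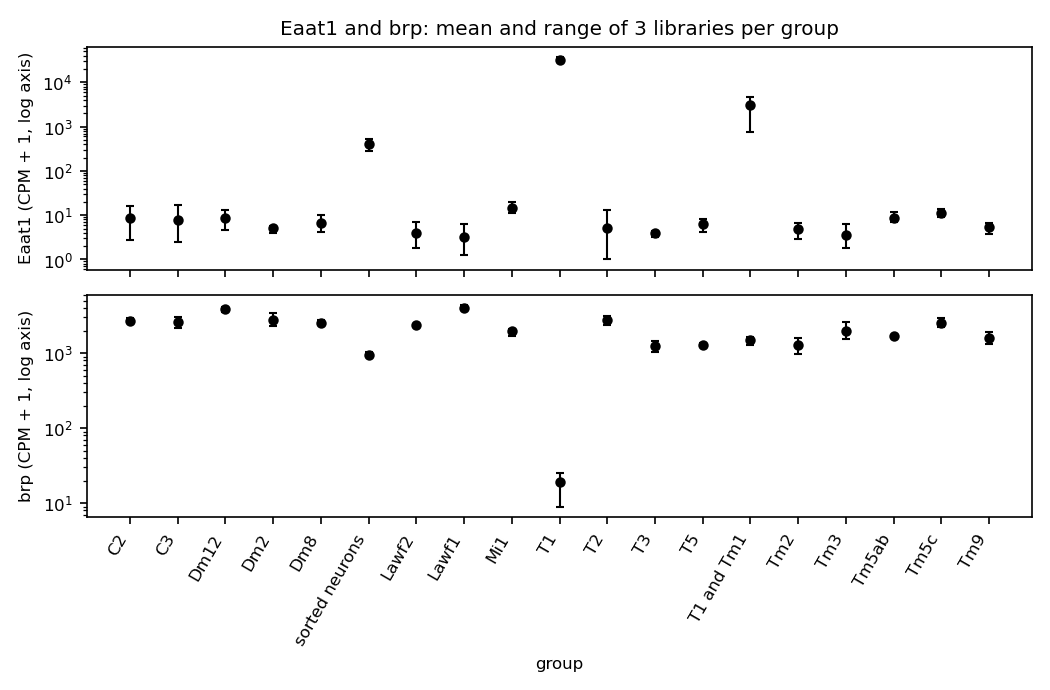
Eaat1 and brp in the 19 groups as CPM + 1 on log axes, with the mean as a point and the range of 3 libraries as a bar. T1 lies apart from the other single types in both genes.

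The comparison among types asks which genes separate them. In the optic lobe cells C2 and C3, C2 had CG17777 at 3696 ± 354 CPM (next 62.2 in T2) and CG14947 at 46.9 ± 18.4, and the homeodomain gene Dll stood at 769.7 ± 30 in C3, 639 ± 4.63 in Dm2 and 449 ± 27.8 in C2. Dm12 had the LIM homeodomain genes CG4328 (736 ± 66.1) and Lmx1a (372 ± 19.1), at most 5.32 and 2.31 elsewhere. Dm2 had the zinc finger factor gene ham (486 ± 70.2, at most 2.58 elsewhere) and the neuropeptide gene Dh31 (582 ± 80.2). Dm8 had Indy, a citrate transporter gene (46.6 ± 13.6), and CG3277 (229 ± 42.8), and the factor gene tj at 203 ± 18.1, which was higher in Dm12 at 289.8 ± 32.1. Lawf1 and Lawf2 shared opa (2132 ± 28.2 and 5044 ± 415) and eya (266 ± 22 and 271 ± 34.1), developmental regulators at most 1.45 and 0.144 in the other types. CG43108 was at 94.2 ± 7.1 in Lawf2, and the clock gene tim was at 2079 ± 106 in Lawf1 and 996 ± 223 in Lawf2. Mi1 had Ugt36E1 (98.7 ± 9.58) beside bsh. T1 had CG32444 (432 ± 57.7), the neuropeptide gene Crz (513 ± 54.3) and the LIM homeodomain gene Awh (1032 ± 134, at most 1.002 elsewhere).

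T5 had CG14340 at 1737 ± 228 CPM and the LIM homeodomain gene Lim1 at 1070 ± 213, followed by 685 ± 67.2 in Lawf2. T3 had the adenylate cyclase gene ACXC (87.2 ± 32.9) and Tep1 (47.4 ± 21.5), and its leading factor gene, Drgx (292 ± 14.7), was higher in T5 (816 ± 58.3). T2 had CG33658 (28.3 ± 11.1), asRNA:CR43152 (104 ± 48.6) and the Hox gene Ubx (27.8 ± 24.7, beside 25.4 ± 23.1 in Tm2). Tm2 had TTLL3A (27.8 ± 12.5), asRNA:CR44370 (128 ± 41.6) and CG11085 (105 ± 3.67). Tm3 had lncRNA:CR45414 (37.6 ± 14.6), the surface protein gene DIP-theta (1250 ± 345) and the POU factor gene vvl (519 ± 170). Tm5ab had CG33673 (46.96 ± 5.88), the peptide receptor gene TkR86C (178 ± 36.4) and the Hox gene Abd-B (17.7 ± 5.44). Tm5c had the LIM homeodomain gene tup (461 ± 51.3, at most 1.17 elsewhere) and lncRNA:CR44794 (27.9 ± 16.2). Tm9 had Wnt10 (329 ± 35.8), ninaC (223 ± 38.8) and dac (391 ± 77.3, beside 361 ± 76.9 in Dm8). Exon bases shared with a neighbour, whose reads cannot be assigned, are 18 percent for CG3277 (Fign), 28.6 for CG32444 (asRNA:CR45955), 19.5 for asRNA:CR43152 (CG15721), 12.6 for DIP-theta (lncRNA:CR44822) and 14.5 for lncRNA:CR44794 (snRNA:U4:25F). In DESeq2 Indy (adjusted p = 0.193), lncRNA:CR45414 (adjusted p = 0.196) and lncRNA:CR44794 (adjusted p = 0.183) did not pass.

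In edgeR's F test over the 17 types, 11431 of 12569 genes (90.9 percent) varied at an adjusted p under 0.05, and 1564 had a range of 5 or more in log2(CPM + 1). Against the mean of the other 16 types, the genes called higher and lower numbered 2807 and 801 in C2, 2051 and 618 in C3, 1326 and 663 in Dm12, 1252 and 366 in Dm2, and 1398 and 426 in Dm8. They numbered 3419 and 961 in Lawf1, 2487 and 609 in Lawf2, 1063 and 476 in Mi1, 1741 and 1280 in T1, 2325 and 2823 in T2, 1210 and 493 in T3, and 1906 and 969 in T5. In the Tm types they numbered 1074 and 605 in Tm2, 1156 and 285 in Tm3, 1745 and 245 in Tm5ab, 2365 and 424 in Tm5c, and 1084 and 372 in Tm9. T2 had the most calls, 5148, but 3550 without its library 1, which is below the 4380 of Lawf1. With the trend of the T2 fold change on exon length taken out, 3142 genes were higher and 1338 lower in T2. The median log2 fold change over all genes was -1.24 in T2. DESeq2 size factors moved that median by -0.12 in Tm9 and by less than 0.1 in the other 16 types.

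The gene lists were fixed beforehand and differed in how far they spread among types. High T2 levels of genes such as nAChRalpha6, Rdl, beat-Ic, dpr1, eag and ChT stand beside T2 libraries with TMM factors of 0.485 to 0.697, against 0.777 or more in the other groups. They also stand beside a T2 fold change that had a median of -2.07 in the shortest and 0.63 in the longest of 5 sets of genes by exon length. Among cell surface families, the Beat and Side list had a median between-type SD of 2.74 in log2(CPM + 1), with 21 of 21 genes past the F test, and beat-Ic stood at 3840 ± 1460 CPM in T2 and 0.471 at its lowest. The Dpr and DIP list had an SD of 2.24 (31 of 32 genes), with DIP-beta at 1428 ± 109 in Lawf2, DIP-eta at 934 ± 282 in Tm5c, dpr1 at 2522 ± 872 in T2 and DIP-gamma at 1678 ± 191 in Dm8. Other adhesion proteins had 1.86 (43 of 43), with klg at 3011 ± 87.1 in Tm5ab and Dscam3 at 4614 ± 1460 in T3. Among receptors, the monoamine list had 2.56 (17 of 17), with Octbeta1R at 3076 ± 166 in C3, 5-HT1A at 1275 ± 56.8 in C2 and Dop2R at 2106 ± 1270 in Tm3. The nicotinic list had 1.71 (10 of 10), with nAChRalpha6 at 26690 ± 3840 in T2, 12680 ± 3260 in T3 and 3.86 at its lowest. The glutamate receptor list had 1.48 (15 of 15), with mGluR at 774 ± 367 in T2. The GABA receptor list had 1.49 (7 of 7), with CG8916 at 873 ± 99.8 in Dm2, Grd (27.5 percent of exon bases in exons of CG5577 on the other strand) at 351 ± 18 in Dm8, GABA-B-R3 at 812 ± 244 in Dm2, and Rdl, a GABA-gated chloride channel gene, at 16980 ± 4240 in T2 and 83.5 ± 2.64 in Dm8. Of the muscarinic receptor genes, mAChR-B was highest in Dm8 at 273 ± 59.5 and mAChR-A in Lawf1 at 4984 ± 1020, and 2 of 3 varied.

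Among 10000 random lists matched on expression, the surface lists and the nicotinic, glutamate and monoamine receptor lists lay at percentile 100, and so did monoamine synthesis (9 of 9 genes varied), other transcription factors (41 of 46, erm at 1623 ± 104 CPM in Tm5c), cytosolic ribosomal proteins (81 of 82), mitochondrially encoded genes (18 of 18) and mitochondrial ribosomal proteins (70 of 70). Homeodomain genes lay at percentile 99.9 (47 of 57; hbn at 1817 ± 308 in C3 and pdm3 at 4629 ± 743 in Tm2), but at 90.0 without Tm5c. GABA receptors lay at 99.8 but at 72.1 without Dm8, and hemocyte genes at 99.9 (9 of 9) but at 30.1 without C2. Photoreceptor genes lay at 99.7 (19 of 21), activity-regulated genes at 97.7 (10 of 10; sr at 842 ± 252 in Lawf2), stress genes at 97.8 (14 of 14; 94.6 without C3) and trachea genes at 96.0 (4 of 5; as low as 91.1 when 1 type, C2, is left out). Neuropeptides lay at 94.7 (26 of 30), but at up to 99.9 when 1 type is left out (T2), with Tk at 3924 ± 797 in Mi1 and sNPF at 2004 ± 462 in Tm5ab. The clock list lay at 91.6 (11 of 11; 97.2 without T2). Lower percentiles were those of innexins (84.0, 7 of 7; shakB at 1781 ± 134 in C2), ion channels (77.1, 29 of 31; eag at 2007 ± 543 in T2), histamine synthesis (72.5, 6 of 6), fat body (40.1, 7 of 7), muscle (38.8, 11 of 11), pan-neuronal genes (37.3, 16 of 16), glia (37.3, 18 of 19), immune peptides (28.6, 5 of 6) and sex-biased transcripts (21.9, 5 of 5). The lists of acetylcholine synthesis (2 of 2 genes varied), glutamate release (1 of 1), GABA synthesis (2 of 2), muscarinic receptors and histamine receptors (2 of 2) were too small for a percentile. In each list, as many genes varied when adjusted over the list alone. These percentiles are across genes, which are not independent replicates.

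Whole profiles placed each of the 51 single-type libraries nearest to its own type. Each type is 1 GEO sample, so this placement shows only that libraries of a sample resemble each other. Across genes, Pearson's r between types ran from 0.734 to 0.965 with a median of 0.911. C2 and C3 were each other's nearest type (r = 0.956). Tm5ab and Tm5c gave r = 0.947 and Lawf1 and Lawf2 0.920. The nearest type to T2 was T3 (r = 0.806), but T2 ranked 16 of 16 as seen from T3. With the 500 genes of largest variance between types the nearest type changed for 5 types: T2 became the nearest to T3 (r = 0.654), Lawf1 to Lawf2 (r = 0.659, in place of C3), T3 to T5, Tm9 to Tm2 and Tm3 to Dm12.

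**Figure D4:**
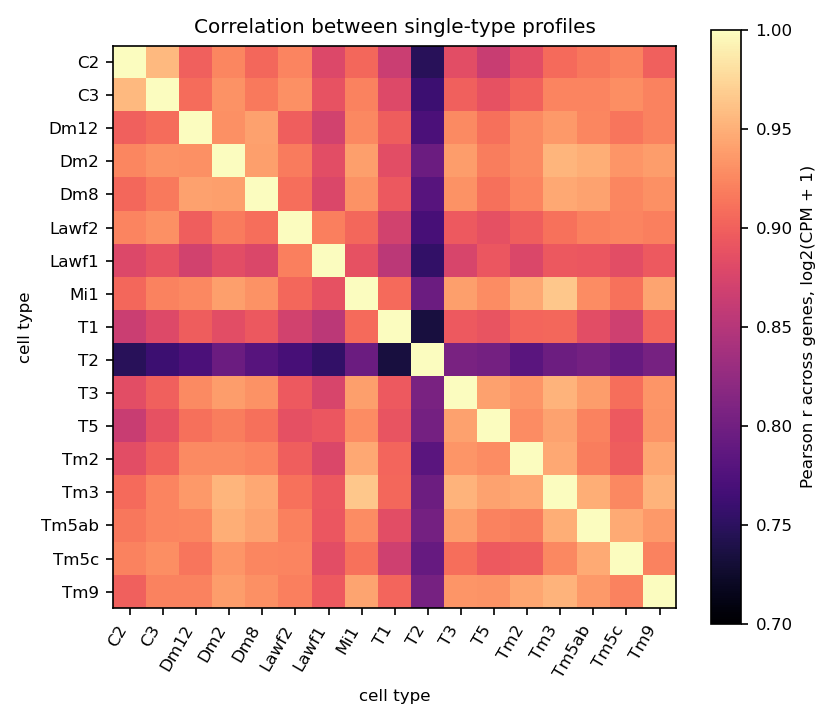
Pearson correlation across genes of log2(CPM + 1) profiles, as colour, between the 17 single types on both axes. C2 and C3 reach 0.956, and T2 has the lowest mean correlation with the others, 0.781.

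The control comparison asks what single types hold or lack beside sorted neurons as a whole. DIP-lambda, a surface protein gene, stood at 51.5 ± 7.36 CPM in sorted neurons and at most 1.34 in a type. The neuropeptide gene CCHa1 stood at 21.1 ± 4.27 against at most 2.05, CG4766 at 24.1 ± 2.22 against 0.558, mab-21, a developmental regulator, at 24.1 ± 6.14 against 0.892, DIP-delta at 22.5 ± 6.41 against 0.575, and CG11294 at 54.9 ± 8.66 against 6.77. In the other direction, the chloride channel gene SecCl averaged 35.2 over the types against 0.156 ± 0.0625 in sorted neurons, the Notch target gene Hey 109 against 0.815 ± 0.766, the heat shock gene Hsp70Bb 88.5 against 2.96 ± 0.954, the collagen gene Col4a1 36.8 against 1.15 ± 0.323, and drd 20.6 against 0.939 ± 0.278. In edgeR the mean of the types was higher for 846 genes and lower for 1957, and the largest adjusted p of the genes named here was 7.3e-07. SecCl did not pass without T1 library 1 (log2 fold change 5.44), nor Col4a1 without T3 library 3 (log2 fold change 3.54). The contrast averages log levels, so genes restricted to 1 type fall by construction. With an arithmetic mean of CPM over the types, tup went from -9.00 to -1.23, Dh31 from -8.66 to -1.15, ham from -7.69 to 0.38 (limma adjusted p = 0.0562) and Vmat from -7.68 to -1.35 (limma adjusted p = 0.0893). That mean, tested with limma on averaged levels, gave 3864 genes higher and 845 lower, with 771 lower both ways and 275 lower in the log fit but higher in it.

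Lists lower in the mean of log levels over the types were, by camera, Dpr and DIP (23 of 32 genes lower, 26 adjusted over the list alone; adjusted p = 1.21e-15), homeodomain genes (29 of 57, 30 adjusted over the list alone; adjusted p = 1.26e-14), Beat and Side (19 of 21 in both; adjusted p = 1.45e-09) and monoamine receptors (15 of 17, 16 adjusted over the list alone; adjusted p = 4.96e-08). Further such lists were other transcription factors (25 of 46, 27 adjusted over the list alone; adjusted p = 5.72e-08), monoamine synthesis (7 of 9 in both; adjusted p = 1.18e-05) and neuropeptides (13 of 30, 14 adjusted over the list alone; adjusted p = 7.43e-05). The trachea list was higher (1 of 5 genes higher and 1 lower in both; adjusted p = 0.000784), and these 8 lists also passed with an estimated correlation. Nicotinic receptors (6 of 10 lower), adhesion proteins (18 of 43 lower) and mitochondrial ribosomal proteins (9 of 70 lower) passed with the preset correlation, with camera adjusted p = 0.0779, 0.458 and 0.753 with an estimated correlation. With the arithmetic mean, none of the 8 lists that passed with both correlations passed, with camera adjusted p = 0.845 for Dpr and DIP, 0.775 for homeodomain genes, 0.957 for Beat and Side, 0.698 for monoamine receptors, 0.727 for other transcription factors, 0.236 for monoamine synthesis, 0.123 for neuropeptides and 0.0837 for trachea, nor did nicotinic receptors (0.972) and adhesion proteins (0.236). Summed CPM was above that of sorted neurons in 10 of 17 types for Dpr and DIP, 15 for homeodomain genes, 14 for Beat and Side, 11 for monoamine receptors, 15 for other transcription factors, 3 for monoamine synthesis and 7 for neuropeptides. The 2 lists that passed with that mean were these: clock genes were higher (adjusted p = 0.0347, 0.841 with an estimated correlation), and mitochondrial ribosomal proteins were lower against other genes (adjusted p = 0.00769, 0.930 with an estimated correlation) with a median log2 fold change of 0.01.

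The line for T1 and Tm1 bears on Tm1, since no group holds Tm1 alone. The mixture had ChAT at 942 ± 81.5 CPM against 7.44 ± 2.72 in T1, brp at 1490 ± 193 against 18.04 ± 8.96, bsh at 123 ± 35.6 against 1.08 ± 1.14 and Gad1 at 464 ± 209 against 25.1 ± 16.2. Since bsh is also the gene used above to check the Mi1 label, Mi1 RNA may be its source in the mixture, which was not tested. Genes of T1 were lower in the mixture: Eaat1 at 3093 ± 2050 against 32110 ± 4550, Awh at 101 ± 63.2 against 1032 ± 134 and Crz at 38.9 ± 25.1 against 513 ± 54.3. Over 16 genes at 200 CPM or more in T1 and at most 1/10 of that in the other types, the mixture held a median of 10.9 percent of the T1 level (quartiles 8.4 and 13.4). These quartiles are across genes, for the mean of the 3 libraries, and do not show the spread between libraries. The sum of glia genes, most of it Eaat1, ran from 972.9 to 4846 CPM between mixture libraries. The genes with the largest rise were sim, a bHLH-PAS factor gene, at 81.1 ± 6.56 with no read in T1, lncRNA:CR44914 at 62.8 ± 14.3 with no read, and CG32572 at 32.97 ± 12.8 with no read, where no read allows up to 0.0454 CPM over the group. Those with the largest fall were the receptor gene mthl8, at 50.96 ± 10 in T1 and no read in the mixture (up to 0.0307 CPM), CG32444 at 432 ± 57.7 against 0.816 ± 1.16, and asRNA:CR45955 at 104 ± 25.7 against 0.495 ± 0.645. RluA-1, a gene chosen after its values were seen, stood at 138 ± 58.5 in the mixture and at most 0.556 in a single type. Of the exon bases of asRNA:CR45955, 54.5 percent lie in exons of CG32444 on the other strand, and 28.6 percent the other way. Reads there cannot be assigned to 1 of the genes, so these may not be separate falls. In edgeR 2172 genes were higher and 1587 lower in the mixture. In DESeq2 CG32444 (log2 fold change -9.12, adjusted p = 0.171) and asRNA:CR45955 (-7.79, adjusted p = 0.549) did not pass.

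Monoamine receptors (13 of 17 genes higher, 3 lower; camera adjusted p = 1.87e-09) and Beat and Side (17 of 21 higher, 3 lower; camera adjusted p = 8.51e-10) rose in the mixture against T1, with the same counts adjusted over the list alone. Both passed with an estimated correlation (camera adjusted p = 0.00119 and 0.00184). Another 13 lists passed with the preset correlation alone. With an estimated correlation, those that rose had camera adjusted p = 0.0610 for glutamate receptors, 0.0626 for Dpr and DIP, 0.0626 for the clock, 0.1 for neuropeptides, 0.137 for nicotinic receptors, 0.179 for other transcription factors, 0.235 for activity-regulated genes, 0.235 for pan-neuronal genes, 0.240 for homeodomain genes and 0.330 for ion channels. Those that fell had 0.138 for glia, 0.520 for stress genes and 0.694 for cytosolic ribosomal proteins.

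Types that share a name stem were compared directly. C3 had more CG31869 (37.4 ± 10.8 against 0.0760 ± 0.0669 CPM), Sidpn (71.5 ± 1.96 against 0.369 ± 0.517) and CG12672 (65.3 ± 16.7 against 0.416 ± 0.327) than C2. C2 had asRNA:CR44106 (66.99 ± 15), the scavenger receptor gene Sr-CI (53.7 ± 16.4) and p-cup (27.04 ± 5.44), with no read, no read and no read in C3 (up to 0.0399 CPM). Gad1 was higher in C3, with a log2 fold change of 1.76 (SE 0.42, adjusted p = 0.00134) in edgeR. That comparison called 617 genes higher and 886 lower in C3, and DESeq2 size factors moved the median of all genes by -0.11. Of the exon bases of asRNA:CR44106, 83.5 percent lie in exons of CG31191 on the other strand, so its reads cannot be assigned to 1 of the genes. In DESeq2 p-cup did not pass (adjusted p = 0.0835). Lawf1 had more TkR86C (93.8 ± 17.2 against 0.0132 ± 0.0229), Lasp (408 ± 13.9 against 0.278 ± 0.481, though in the annotation used here its exon bases all lie in exons of CG43954) and CG32683 (5537 ± 438 against 9.89 ± 5.55) than Lawf2. Lawf2 had nvy, a corepressor gene (788 ± 96.4), and CG12699 (78.9 ± 5.03), with no read and no read in Lawf1 (up to 0.068 CPM), and more mtt, a receptor gene (362 ± 17.6 against 0.257 ± 0.282). In edgeR 2310 genes were higher and 1447 lower in Lawf1.

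Tm5ab had the heat shock cognate gene Hsc70-2 (20.1 ± 8.41 CPM, with no read in Tm5c, which allows up to 0.0614 CPM), more beat-Vb (70.1 ± 9.84 against 0.0321 ± 0.0556) and more of the neuropeptide gene sNPF (2004 ± 462 against 1.18 ± 0.757) than Tm5c. Tm5c had lncRNA:CR44794 (27.9 ± 16.2 with no read in Tm5ab, which allows up to 0.038 CPM) and CBP (31.9 ± 5.12 against 0.0131 ± 0.0228). ChAT and VGlut also split this pair, with 440.1 ± 35.7 and 9.05 ± 4.63 in Tm5ab against 2.17 ± 2.17 and 2292 ± 599 in Tm5c. In edgeR 729 genes were higher and 1193 lower in Tm5ab, and in DESeq2 Hsc70-2 (adjusted p = 0.462) and lncRNA:CR44794 (adjusted p = 0.395) did not pass. T2 had otk (101 ± 56), beat-Va (111 ± 19.7) and Crg-1 (77.2 ± 57.2), with no read of any of these in T3 (up to 0.0405 CPM), and 26.7 percent of the exon bases of Crg-1 lie in exons of lncRNA:CR44117 on the other strand. T3 had the surface protein gene beat-IIa (622 ± 113), the peptide receptor gene Dh44-R1 (286 ± 60.6) and the adenylate cyclase gene Ac78C (264 ± 64), with no read in T2 (up to 0.47 CPM). In edgeR 2156 genes were higher and 3027 lower in T2, and the total of 5183 was 3528 without T2 library 1.

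With the type as the unit, edgeR called 0 genes between the name classes. Drgx averaged 335 CPM over the 4 T types and 0.384 over the 5 Tm types (edgeR adjusted p = 0.165), the POU factor gene acj6 688 and 2.57 (edgeR adjusted p = 0.267; T1, at 0.892 ± 0.0643, lay within the range of the Tm types), and eys, a gene of the photoreceptor list, 12.9 and 1975 (edgeR adjusted p = 0.290). These 3 genes were chosen after their values were seen. Between Tm and T types 1173 genes had an unadjusted p under 0.05, DESeq2 called 169 genes and limma 0, and edgeR called 4 without T1. CG14877 averaged 0.0569 over the Tm types and 4.12 over the 3 Dm types, with the lowest edgeR adjusted p of that comparison, 0.0504, and was also chosen after its values were seen. Between Tm and Dm types 1039 genes had an unadjusted p under 0.05, DESeq2 called 95 genes and limma 0, and edgeR called 2 without Dm12 and 1 without Dm2, Dm8 or Tm5c. Mitochondrially encoded genes had a median log2 fold change of -2.06 in Tm against T types (camera adjusted p = 1.12e-07; 0 genes lower over all genes tested, 15 of 18 adjusted over the list alone) and of 1.14 in Tm against Dm types (camera adjusted p = 1.48e-09; 0 genes higher over all genes, 10 adjusted over the list alone). With an estimated correlation the camera adjusted p was 0.976 and 0.733. Their sums in T types ran from 5498 ± 1900 CPM in T3, below the lowest Tm type, Tm3, at 7292 ± 3580, to 121000 ± 19700 in T2, whose libraries had TMM factors of 0.485 to 0.697. Adhesion proteins and pan-neuronal genes (lower) and mitochondrial ribosomal proteins (higher) passed in Tm against T types, and mitochondrial ribosomal proteins (higher) in Tm against Dm types, with camera adjusted p = 0.976 and 0.945 with an estimated correlation.

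Markers of other cells and of stress were summed over each list. Glia genes summed to 32550 ± 4500 CPM in T1, most of it Eaat1, to 3321 ± 2060 in the mixture, to 798 ± 157 in sorted neurons, and in the other types to between 190.4 ± 34.9 in Mi1 and 1223 ± 78.2 in Lawf1. Photoreceptor genes summed to 6290 ± 1230 in T2, where rdgA stood at 4142 ± 846, and to 1489 ± 94 in sorted neurons. Hemocyte genes summed to 794 ± 42.6 in Mi1, where Pxn stood at 644 ± 42.9, to 709 ± 39.6 in C3 and to 207 ± 13 in sorted neurons. Their sum was above that of sorted neurons in 12 of 17 types. Trachea genes summed to 218 ± 18.6 in Lawf2, where serp stood at 169.6 ± 8.85, against 1.58 ± 0.697 in sorted neurons. Near Lawf2 were C2 (214 ± 47.3), Tm5c (199 ± 50.4) and C3 (182 ± 32.3), and 15 of 17 types lay above sorted neurons. Stress genes ran from 1623 ± 187 in T2 to 5995 ± 1330 in Dm12, with Hsp23 highest in T1 at 255 ± 136. Fat body genes reached 282 ± 114 in T2, beside 271 ± 21.9 in Lawf2. Muscle genes reached 30.3 ± 22 in T2, with libraries from 9.53 to 53.3. Sex-biased transcripts reached 103 ± 91.4 in Tm9, with libraries from 19.1 to 200.3, and immune peptides 15.5 ± 0.577 in Lawf1. The T2 sums stand beside the TMM factors and the length trend of T2 given above. Pan-neuronal genes summed to 78080 ± 14200 in T2 and to between 18910 ± 372 in T1 and 34790 ± 3240 in Lawf1 in the other types. Mitochondrially encoded genes ran from 5326 ± 1130 in Dm12 to 121000 ± 19700 in T2, and cytosolic ribosomal protein genes from 3083 ± 1060 in T2 to 24490 ± 1050 in Lawf1.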

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

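The tests of glial RNA and of RNA loss in T1 and of C2 and C3 RNA in the mixture were chosen after the results were seen. For reads and gene length in T2, the predictions were written before the results of those tests were seen. Thinning, the test of reads, was itself chosen after seeing the data.

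Among types of a name class, 5 of 41 groups tested held a value far from the others. The rule used flags about 1 in 20 groups of independent, normally distributed values. These groups reuse the same types, and transmitter genes split the types into sets, so that rate does not apply. The 5 of 41 is thus not read as an excess. ChAT was at 2.17 CPM in Tm5c, with the next Tm type at 440.1, and at 7.44 CPM in T1, with the next T type at 403. CG30345 was highest of the T types in T2 at 0.961 ± 1.66 CPM, from 1 library at 2.88 with no read in the others, and Balat in T1 at 2.14 CPM. T2 had 12.6 M reads in genes over its libraries, with the next T type at 64.7 M.

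Counting summaries that no comparison uses lay in some groups above the highest sorted-neuron library. Reads in no feature were at a mean of 48.9 percent in T3, against at most 48.0 percent in sorted neurons. That is a small gap, since these reads ran from 40.47 to 49.19 percent over all 57 libraries, with a median of 47.37. Ambiguous reads were at 1.33 percent in C2, 1.23 in C3, 1.31 in Dm12, 1.26 in Dm2, 1.29 in Dm8, 1.64 in Lawf1, 1.21 in Lawf2, 1.49 in T5, 1.16 in Tm3, 1.23 in Tm5ab and 1.26 in Tm9, against at most 1.09 in sorted neurons. Reads without a unique alignment were at 20.6 percent in T1, 16.1 in Lawf1, 14.9 in T2, 12.8 in Lawf2, 11.3 in T5 and 11.5 in the mixture, against at most 10.3 in sorted neurons. No explanation of these was tested.

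Eaat1 was far higher (32110 ± 4550 CPM) and brp far lower (18.04 ± 8.96) in T1 than in the other 16 types. A first test of glial RNA, the median log2 fold change of 18 other glia genes, was undecided at 0.60 (quartiles -0.82 and 1.19). The ratio of Eaat1 to the astrocyte gene alrm, taken up after it, was at least 1895 in T1 libraries. It was at most 10.4 in the 47 libraries of the other types with an alrm read and at most 35.3 in sorted neurons. These ratios argue only against a source of Eaat1 whose ratio is like that in the other libraries. No group holds astrocytes, so the ratio of astrocyte RNA is not known here, and astrocyte RNA is not excluded. The ratios also rest on 1 astrocyte gene, so they cannot speak to glia with little alrm. In addition, alrm and 5 other glia genes were higher in T1, and a small share of glial RNA is not excluded. The 15 other pan-neuronal genes had a median log2 fold change of -0.45, against -6.91 for brp, and 8 of them were lower. Relative to other genes, they thus did not fall as far as brp as a set, and a smaller relative loss is not excluded. Levels are scaled per library, so a loss shared by all genes would not show. The test therefore cannot decide on a general loss of RNA. In the mixture, a separate line that also labels T1, Eaat1 stood at 3093 ± 2050 CPM. That T1 cells may carry much Eaat1 and little brp stays a hypothesis, and a wrong label was not tested.

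Gad1 was at 464 ± 209 CPM in the mixture against 25.1 ± 16.2 in T1, which is 11.9 percent of its C2 level and 3.50 percent of its C3 level. The 17 genes at 20 CPM or more in C2 and at most 1/10 of that outside C2 and C3 stood at a median of 0.318 percent of their C2 level (upper quartile 2.14, CG14989 23.0), which argues against C2 as the whole source. For C3 only 3 such genes were found, Cyp18a1 at 0.0407, Pvr at 2.51 and CG14989 at 5.44 percent, with a median of 2.51 percent, too few to decide. Both thresholds were chosen after several had been seen: over 10 settings the C2 medians ran from 0.262 to 3.22 percent, 0 of 10 at 1/2 of the Gad1 share or more, and the C3 medians from 2.05 to 5.44 percent over 1 to 12 genes, 10 of 10 at 1/2 of the share or more. C3 RNA may thus be a source, and Tm1 cells, which no group holds alone, were not tested.

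T2 had the most genes called, 5148, from its 12.6 M reads. With every library thinned to the shallowest, which left 7351 genes tested, T2 still had 4633 calls against 2489 in Lawf1. That argues against the number of reads alone as the cause. Thinning does not even out how many molecules a library sampled, so it cannot speak to that. The T2 fold change followed gene length, with medians of -2.07, -2.11, -1.85, -0.90 and 0.63 over 5 sets of genes from the shortest to the longest. With that trend taken out T2 still had the most calls, 4480 (3142 higher and 1338 lower, from 2325 and 2823) against 4300 in Lawf1, but the lead is smaller than the range of 3550 to 5128 when 1 T2 library is left out, a yardstick taken after the value was seen, so a length trend cannot be told apart from other causes. A difference between the cell types is also open and was not tested.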

How the results depend on the processing

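Thinned libraries, fits without T2 and the arithmetic mean over types were chosen after seeing the data. A count was taken as unmoved within 1.5-fold of the main count, or at 0 where that was 0. A correlation was taken as unmoved when it kept its sign and its side of the threshold. With DESeq2 size factors 28 of 29 counts and correlations were unmoved, with DESeq2 25 of 27, with no filter 25 of 27, with limma-voom 21 of 25 and without T2 23 of 23. For each that moved, the cause was not tested unless stated. Named genes kept their direction except ham. limma-voom called 3714 genes in Dm12, 4007 in T3, 3583 in Tm2 and 5492 against sorted neurons. Thinning left 7351 genes tested, against 12569 in the main fit, so its counts are also out of fewer genes. Thinned to the shallowest library, fewer reads gave 1653 in C2, 1234 in C3, 1062 in Dm12, 888 in Dm2, 929 in Dm8, 2489 in Lawf1, 1342 in Lawf2, 885 in Mi1, 1881 in T1, 937 in T3, 1086 in Tm2, 785 in Tm3, 903 in Tm5ab, 1233 in Tm5c, 769 in Tm9, 24768 summed over types, 7118 in the F test, 1808 against sorted neurons, 2102 in the mixture, 782 between C3 and C2, 2380 between Lawf1 and Lawf2 and 923 between Tm5ab and Tm5c. With 1 profile per type, where the construction leaves 1 sample against the others, calls were 65 in C2, 12 in C3, 18 in Dm12, 16 in Dm2, 51 in Dm8, 302 in Lawf1, 51 in Lawf2, 9 in Mi1, 158 in T1, 9 in T3, 14 in T5, 13 in Tm2, 10 in Tm3, 21 in Tm5ab, 98 in Tm5c, 6 in Tm9, 3563 in T2, 4416 summed over types and 21 against sorted neurons, where ham reversed to 0.34. Between Tm and T types no filter gave 1 gene and DESeq2 169; between Tm and Dm types DESeq2 size factors gave 1, no filter 1 and DESeq2 95. The arithmetic mean over types, which changes the weight of a gene and also the test, to limma, gave 4709 genes and 2 lists against sorted neurons, and ham at 0.38. An estimated correlation left 2 lists in the mixture, 0 in Tm against T types and 0 in Tm against Dm types. Leaving out 1 type gave 0 to 4 genes between Tm and T types and 0 to 2 between Tm and Dm types. Leaving out 1 library gave 3550 to 5128 genes in T2, 3528 to 5159 between T2 and T3 and 2161 to 3155 against sorted neurons. Of named genes, 10 of 125 no longer passed in DESeq2 (Cks30A and asRNA:CR45371 in the mixture among them), 4 of 120 when thinned and 32 of 65 with 1 profile per type. Thinned, CCHa1, CG33658, Abd-B and lncRNA:CR44794 fell under the filter and gave no value, as did Ubx with T2 and T3 alone.

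With the library number as a replicate block, calls were 2808 for the mean of the 17 single types against sorted neurons, 3706 for the T1 and Tm1 mixture against T1, 1489 between C3 and C2, 3735 between Lawf1 and Lawf2, 1895 between Tm5ab and Tm5c and 5196 between T2 and T3. Libraries of the same number correlated between -0.043 and 0.054 across genes after group means, so the block was not used.

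Depth limits T2 most, where a level of 0 allows up to 0.47 CPM.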

Other observations

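The count of splits for the sum over the types was chosen after the result was seen; the other split counts were planned. Other splits of the libraries were fitted to see whether chance labels give as many genes. For the F test, 1 of 100 splits, the real one, gave 11431 genes, and the highest other gave 2081. The other splits mix libraries of different samples, so these counts show only that libraries of a sample resemble each other. For the types against sorted neurons, 1 of 100 gave 2803, and the highest other gave 1568, with the same limit. Each group is 1 GEO sample, so chance differences between samples are not tested by these splits, and with 1 profile per type 21 genes were called against sorted neurons. The fewest calls of any type were 1441, in Tm3. In each other split the calls of 1 type were counted, a different type in turn. With the real one included, 6 of 100 splits gave at least 1441, and the highest other gave 2248. This sets the fewest calls of 17 types against 1 type per split. Chance cannot be excluded by that count, which also does not test Tm3 itself. Of those 5 other splits, 2 put a T2 library in the relabelled type. The sum over the types was 42825, and 1 of 30 splits gave as many, with a highest other of 6631.

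With 3 libraries against 3 there are 10 splits, so the share is never under 0.1. In each pair 1 of 10 splits, the real one, gave the real count: 3759 in the mixture against T1 (highest other 143), 1503 between C3 and C2 (7), 3757 between Lawf1 and Lawf2 (19), 1922 between Tm5ab and Tm5c (44) and 5183 between T2 and T3 (1662). Between Tm and T types 100 of 100 splits gave at least the 0 genes of the real one, with a highest other of 5, and between Tm and Dm types 56 of 56, with a highest other of 33. Every split reaches a count of 0, so these splits say nothing about chance.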
